A study of Musa acuminata AAA Group with 12 samples.

How the data were processed

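RNA was measured in roots of banana plantlets (Musa acuminata AAA group, cultivar Pisang ambon kuning) grown in a split-root assay, in which 1 part of the root system received endophytic bacteria and another part received Foc TR4, the tropical race 4 form of the Fusarium fungus that causes banana wilt. The 12 libraries crossed 3 inoculations (no endophyte, isolate BR-49 labelled S. nitritireducens, isolate SL-08 labelled K. rhizophila) with 4 stages: roots of uninfected plants 72 h after inoculation, and roots 6, 24 and 72 h after infection. Each library was a pool of 3 biological replicates, per the labels, and each combination had 1 library. Which part of the divided root was sampled is not given in the sources used here.

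The deposited FPKM values (fragments scaled for locus length and library size) were made by the authors with TopHat and Cufflinks 2.2.1 after FastQC, per the submitters' processing notes; the versions of TopHat and FastQC, the genome build and the settings are not given in the sources used here. Each deposited file listed the loci of 1 library with an FPKM and the lower and upper bound of its interval. Loci were numbered anew in each file, had no gene name and no strand, and had no value of 0. Overlapping genes and near-identical copies therefore cannot be separated, and a locus absent from a file has either no transcript found or a value that was left out upstream. The gene table at hand describes another assembly, gives only locus numbers as symbols, and was not used for coordinates or names. The 45 gene lists fixed before the data were examined are void, because no locus could be paired with a gene name, and 0 of them were tested. Positions are given as listed in the files, as medians over the libraries.

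Libraries were joined by position. Of the 359824 listed loci, 353260 spanned at least 300 bp and were used, because shorter loci carried FPKM of up to 4.70e+09. Loci of different libraries were joined where they overlapped by at least 50% of the longer one, which gave 49402 joined loci. Of these, 1911 held more than 1 locus of a library and were left out. A further 23428 were left out because at least 1 library had a locus of another shape there, which is 49.3% of the 47491 loci with 1 member per library. The remaining 24063 were given the value 0 in a library with nothing listed there. The overlap and the length minimum were chosen after the files were seen and before any test was run; joining at 80% and 90% overlap and using only the 18462 loci listed in all 12 libraries were added as alternatives after seeing the data.

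FPKM were divided by a scale factor per library, the median ratio to the geometric mean over loci with FPKM of at least 1 in all 12 libraries (0.816 to 1.26), and log2(FPKM + 1) was taken. Fold changes are on that scale and understate the change of low loci. Scaling shifted the median log2 change of all loci for the infection comparisons, which was between -0.27 and -0.21 with FPKM as deposited and between -0.04 and -0.02 after scaling. The 21687 loci with FPKM of at least 1 in at least 3 libraries were tested with limma 3.58.1 (trend and robust empirical Bayes, statmod 1.5.0, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model held stage and inoculation as additive terms over all 12 libraries and left 6 residual degrees of freedom. A second model added the interaction of inoculation with infection and left 4. Because no combination had a second library, these p-values judge each effect against the departure from additivity among single pooled libraries. An effect present at 1 stage alone is not called by the additive model. Infection cannot be separated from time, since an uninfected library was analysed only at the first stage. Comparisons of 2 libraries had no replicate check and no test: loci were counted at a log2 ratio of at least 1 in either direction with a scaled FPKM of at least 5 in 1 of the 2 libraries. The share of variance by factor was tested by permuting the labels of a factor within the levels of the other, with 100000 draws; full enumeration of the arrangements was added after seeing the data.

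The test was tried on simulated data with normal noise, independent between loci and libraries, at the empirical Bayes spread that limma fitted for each locus. No library lay apart and no loci moved together in these data, so recovery in the real data may differ. The changed loci were drawn among those with a mean level above 5. With 200 of 21687 loci changed by 2 log2 units, 178 (89%) were recovered for BR-49 against no endophyte with 6 false calls, and 170 (85%) for 6 h after infection against before with 10 false calls. At 1 log2 unit, 0 of the 200 were recovered in either comparison. At 3 log2 units, 198 and 194 were recovered.

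The named loci followed a rule fixed before the data were examined: among loci past the threshold with a mean scaled FPKM of at least 5, the largest changes, and where fewer than 5 passed in a direction, the smallest p-values. The rule also asked for a gene product, which could not be applied, and because no names could be paired, at most 2 loci per direction are given for a comparison. Alternatives fixed in advance were a pseudocount of 0.1, no scaling, quantile normalization, no filter, a filter at FPKM of 5, non-robust empirical Bayes, infected libraries alone, no block, and leaving out each library in turn. Joining and description used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

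The files gave no read totals. The interval of each FPKM implied a fragment number, namely the square of 2 times the FPKM divided by the distance from the FPKM to its upper bound. Summed over the loci of at least 300 bp these came to between 8506025 and 14909209 per library. They are a description of precision and not counts: of implied numbers under 50, between 31.2% and 34.4% lay within 0.05 of a whole number. Among loci with FPKM of at least 5, the median distance from FPKM to its upper bound was between 9.27% and 12.9% of the FPKM, which covers the authors' estimate of a single library and not variation between plants.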

Results

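The series measured the root transcriptome of banana plantlets that were first inoculated with an endophytic bacterium, or with none, and then infected with Foc TR4, the fungus of Fusarium wilt, in another part of a divided root system. Of the 12 pooled libraries, 3 came from uninfected plants and 9 from infected plants. Infected, uninfected and inoculated roots below are roots of such plants, since the part of the root system that was sampled is not given in the sources used here. The files listed between 28046 loci (no endophyte, 24 h after infection) and 32862 loci (no endophyte, uninfected), and the implied fragment numbers of these same libraries were the lowest and the highest, 8506025 and 14909209. The locus of highest mean level lay on chromosome 1 at 7536232 to 7536762, with a scaled FPKM of 16196 ± 9739 (SD, n = 12). It stood at 33229 with BR-49 and 33360 with SL-08 at 24 h after infection, and at 5118 without endophyte at that stage, in the library that lay apart from the rest. At 72 h it stood at 21208 without endophyte, 18933 with BR-49 and 20019 with SL-08. A locus on chromosome 3 at 19115215 to 19115864 had the opposite order at 24 h, with 35389 without endophyte, 2687 with BR-49 and 3324 with SL-08, but this order rests on the same library: in uninfected plants it stood at 5991 without endophyte and 23905 with BR-49.

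Roots of infected plants were compared with roots before infection to describe the changes over 6, 24 and 72 h. Uninfected roots were analysed only at the first stage, so infection cannot be separated from time. An infection response below means the change from that stage, whatever its cause. At 6 h, 14 of 21687 loci passed the threshold, 8 higher and 6 lower. All 14 moved in the same direction in the 3 inoculations. The test takes its spread from disagreement between the inoculations, so this agreement follows largely from the choice of loci. On chromosome 11, the locus at 525245 to 526043 rose by a log2 fold change of 3.87 ± 0.41 (SE; limma adjusted p = 0.022), from 0.848 ± 0.788 to 25.7 ± 11.5 scaled FPKM (SD, n = 3), although it was not listed in 1 of the 3 uninfected libraries. With a pseudocount of 0.1 its log2 fold change was 5.42 and it was not called (limma adjusted p = 0.103), and 6 of the 14 loci were called; the cause was not tested. On chromosome 10, the locus at 7616450 to 7617728 rose by 3.31 ± 0.32 (SE; limma adjusted p = 0.022), from 2.62 ± 0.953 to 34.9 ± 9.49, and stood at 26.1 ± 6.84 at 24 h and 4.48 ± 1.78 at 72 h. Among the loci that fell, the one on chromosome 9 at 29942531 to 29946240 went from 37.1 ± 6.81 to 3.93 ± 0.636, a log2 fold change of -2.95 ± 0.32 (limma adjusted p = 0.022), and stood at 49.1 ± 6.50 at 72 h. Another on chromosome 9, at 35114071 to 35115271, went from 12.6 ± 5.72 to 1.27 ± 0.233 (log2 fold change -2.50 ± 0.31, limma adjusted p = 0.0375) and stood at 13.1 ± 5.13 at 72 h. Of the 14 loci, 11 were listed in all 12 libraries. The count of 14 was 0 without either the no-endophyte or the SL-08 uninfected library, without any of the 3 libraries at 6 h, or without any of the 3 at 72 h; it was 5 without the uninfected BR-49 library (4 of them among the 14) and 50 (29 higher, 21 lower) without the no-endophyte library at 24 h, which lay apart from the rest. With FPKM as deposited, 14 loci were called again, 4 higher and 10 lower, of which 10 were among the 14 above.

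At 24 h after infection, 4 loci passed the threshold, 2 higher and 2 lower, and all 4 were among the 14 called at 6 h. With a pseudocount of 0.1, or with a filter at FPKM 5, the count was 0. The chromosome 10 locus at 7616450 to 7617728 rose by 2.91 ± 0.32 (SE; limma adjusted p = 0.0389). On chromosome 5, the locus at 5017708 to 5018816 rose by 2.38 ± 0.26 (SE; limma adjusted p = 0.0389), from 1.77 ± 0.452 before infection to 13.7 ± 4.28, and stood at 3.10 ± 0.811 at 72 h. The pair of loci called lower lay outside the rule for naming and was chosen after the values were seen. These loci, on chromosome 9 at 31843269 to 31843744 and on chromosome 11 at 26149717 to 26157311, were listed in all 3 uninfected libraries, at 6.04 ± 0.733 and 5.62 ± 0.970 (SD, n = 3), and in none of the libraries at 6 or 24 h, so that no fold is given. The first was not listed at 72 h either, and the second stood at 5.49 ± 2.02 there. The count of 4 at 24 h was 0 with each library left out in turn, except without the uninfected BR-49 library, where 4 loci were called, all higher, and 2 of these were among the 4 above.

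At 72 h after infection, limma called 0 loci, with 2180 of 21687 at an unadjusted p under 0.05. For independent loci without effect 1084 would follow. The number was 3020 at 6 h, 2606 at 24 h and 565 for SL-08 against BR-49, so 1084 is no firm reference. The smallest p-values at a mean scaled FPKM of at least 5 belonged to a locus on chromosome 3 at 6675602 to 6677652, with a log2 fold change of 1.42 ± 0.23 (SE; limma adjusted p = 0.316), and to one on chromosome 5 at 32538972 to 32552070, with -1.51 ± 0.24 (limma adjusted p = 0.316). Without the uninfected BR-49 library the count was 1. The 14 loci called at 6 h had fitted changes in the same direction at 24 h, of at least 1 log2 unit for 12 of them. Both comparisons use the same uninfected libraries, so that this agreement is expected in part. At 72 h 11 of the 14 lay within 1 log2 unit of the level before infection.

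**Figure D1:**
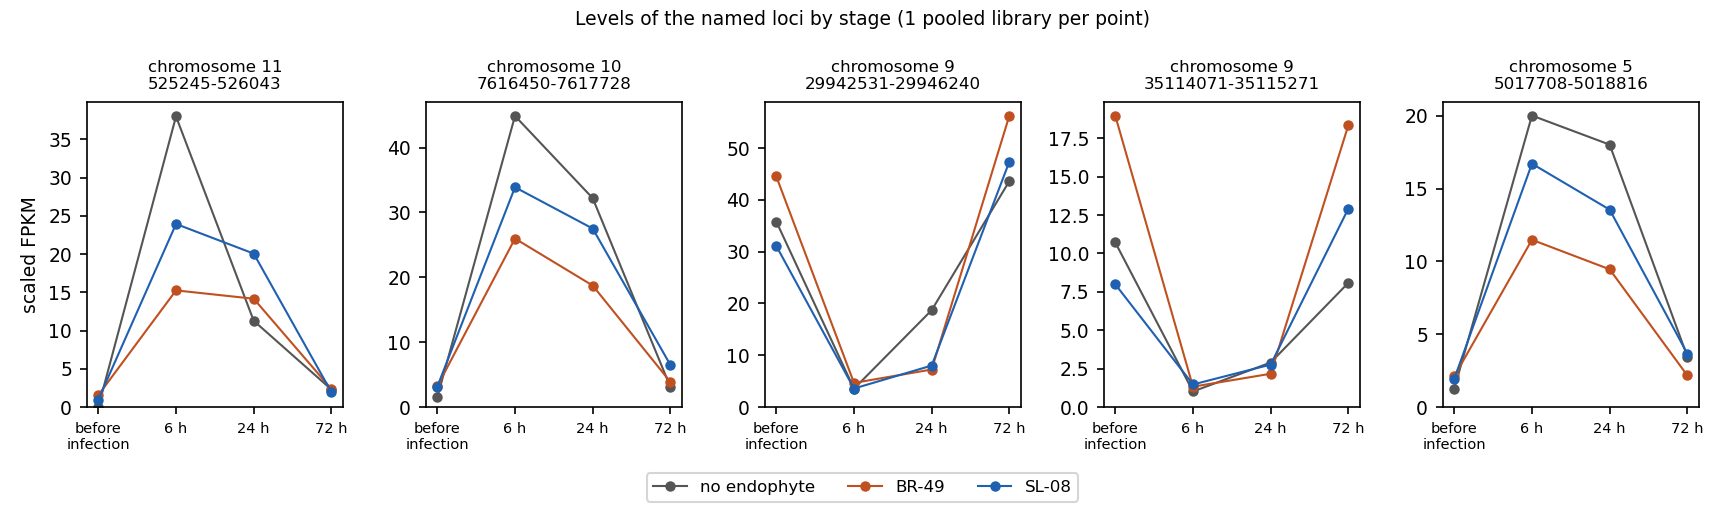
Scaled FPKM (vertical axis) of the 5 named loci that passed the threshold at 6 or 24 h after infection, at each stage (horizontal axis), with 1 line per inoculation and 1 pooled library per point; the point at 0 for the chromosome 11 locus without endophyte before infection means that it was not listed there. The locus on chromosome 10 at 7616450 averaged 2.62 before infection, 34.9 at 6 h and 4.48 at 72 h, and the locus on chromosome 9 at 29942531 averaged 37.1, 3.93 and 49.1.

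Roots of inoculated plants were compared with roots of plants without endophyte, over the 4 stages, to ask what each bacterium changed. No locus passed the threshold. For BR-49, limma called 0 loci, with 1139 at an unadjusted p under 0.05 and a smallest adjusted p of 0.92. The smallest p-values belonged to the locus on chromosome 1 at 12782318 to 12783508, with a log2 fold change of 1.40 ± 0.24 (SE), and on the lower side to the locus on chromosome 4 at 34584987 to 34585969, with -0.83 ± 0.19. For SL-08, limma called 0 loci, with 925 at an unadjusted p under 0.05 and a smallest adjusted p of 0.927. A locus on chromosome 7 at 29524906 to 29526069 had a log2 fold change of 1.73 ± 0.27 (SE), and a locus on chromosome 4 at 25979598 to 25983084 had -1.44 ± 0.23. In the direct comparison of SL-08 with BR-49, limma called 0 loci, with 565 at an unadjusted p under 0.05. There, a locus on chromosome 9 at 38146521 to 38148237 had 0.91 ± 0.17, and a locus on chromosome 2 at 14364674 to 14367736 had -1.30 ± 0.23. These counts stayed at 0 under every alternative run. In the simulated data for BR-49, 0 of 200 changes of 1 log2 unit were recovered. The counts of 0 therefore do not exclude changes of that size. Larger changes in few loci are not excluded either. The simulated data had 200 loci changed together and no library apart, and the adjustment depends on how many loci change.

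The split-root design asks whether earlier inoculation alters the response to infection, and the difference between the endophyte effect in infected and in uninfected roots was tested. Each inoculation has 1 uninfected library, which this model fits exactly, so the spread comes from the 9 infected libraries and the lone library is assumed to vary like them. The median SE of these differences was 0.582, against 0.272 for the endophyte comparisons over the 4 stages. The simulated data did not cover this model. A count of 0 here therefore does not show that inoculation left the response unaltered. Limma called 0 loci for BR-49 (1031 at an unadjusted p under 0.05, smallest adjusted p = 0.0759) and 0 for SL-08 (966, smallest adjusted p = 0.0679). The smallest p-values of both belonged to 2 loci that were not listed in the uninfected no-endophyte library. On chromosome 2, the locus at 14637834 to 14661963 had scaled FPKM between 19.2 and 25.7 in the other 11 libraries, and the locus on chromosome 4 at 4178897 to 4185607 had between 13.2 and 19.0. A locus on chromosome 9 at 1585211 to 1592770 had 66.2 in the uninfected no-endophyte library and between 2.79 and 5.02 in the other 11, with a log2 difference of 3.56 ± 0.41 for BR-49 (limma adjusted p = 0.357) and 4.26 ± 0.41 for SL-08 (limma adjusted p = 0.111). These 3 loci are thus departures of that single library. Without the no-endophyte library at 72 h after infection, the count for BR-49 was 1, at a locus not listed in every library.

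Each inoculated library was then set beside the library without endophyte of its stage. These comparisons, and those within an inoculation, hold 1 library on each side and have no replicate check. In uninfected roots, 1458 loci were at least 2-fold higher and 1573 lower with BR-49 (1035 and 2474 with FPKM as deposited), and 1095 were higher and 1424 lower with SL-08 (676 and 2531). At 6 h after infection the counts were 993 and 454 for BR-49 (1229 and 326 as deposited) and 458 and 488 for SL-08 (244 and 940). At 24 h they were 2286 and 2174 for BR-49 (2778 and 1615) and 2007 and 1939 for SL-08 (2986 and 1256), both against the no-endophyte library that lay apart. At 72 h they were 695 and 845 for BR-49 (369 and 1604) and 481 and 380 for SL-08 (370 and 596). Between the bacteria, a set of comparisons added after seeing the data, 1792 loci were higher and 2031 lower with SL-08 than with BR-49 in uninfected roots, 587 and 1223 at 6 h, 457 and 507 at 24 h, and 353 and 480 at 72 h. Of the loci counted and listed in both libraries, between 94.0% and 97.7% had intervals that did not overlap. This follows largely from the counting at 2-fold, since the median distance from FPKM to its upper bound was at most 12.9% of the FPKM. Those intervals cover the authors' estimate of a single library and not variation between plants.

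Of the 84 loci that the rule of size picked from the comparisons of 2 libraries, 74 were not listed in 1 of the 2, and no fold is given for those. Loci listed on both sides were therefore named instead, a choice made after the values were seen. In uninfected roots, the chromosome 10 locus at 14466394 to 14468422 stood at 435 scaled FPKM (interval 422 to 449) with BR-49 and at 19.9 (18.3 to 21.6) without endophyte; the other 3 BR-49 libraries had 6.46, 10.7 and 43.0. On chromosome 5, the locus at 6186054 to 6190646 stood at 197 without endophyte, 14.4 with BR-49 and 3.98 with SL-08; the other 3 no-endophyte libraries had 4.66, 13.4 and 5.52, so the departure was in 1 library. Also on chromosome 5, the locus at 24234534 to 24236200 stood at 38.1 with SL-08 and 0.966 without endophyte, while the other 3 SL-08 libraries had 1.49, 10.8 and 4.14 and the BR-49 library at 6 h had 30.0. At 24 h after infection, a pair of loci on chromosome 10 was low in the no-endophyte library, the one that lay apart. The locus at 23982297 to 23982751 stood at 15.5 there against 2333 with BR-49 and 2653 with SL-08, and the locus at 23973470 to 23974289 stood at 9.09 against 953 with BR-49; the other 3 no-endophyte libraries had 2526, 587 and 1198 for the first and 1883, 220 and 225 for the second. On the other side, the locus on chromosome 11 at 25739617 to 25740562 stood at 1270 without endophyte, 3.30 with BR-49 and 3.52 with SL-08, where the other 3 no-endophyte libraries had 46.1, 1.94 and 1.72. At 72 h, the locus on chromosome 3 at 28598931 to 28600434 stood at 299 (286 to 311) with BR-49, 251 (239 to 263) with SL-08 and 13.6 (11.9 to 15.3) without endophyte, where the other 3 no-endophyte libraries had 210, 390 and 462.

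Within each inoculation, infected roots were set beside uninfected roots. Without endophyte, 2006 loci were at least 2-fold higher and 2134 lower at 6 h (1032 and 4200 with FPKM as deposited), 2883 and 2997 at 24 h (1332 and 6019), in the library that lay apart, and 754 and 1068 at 72 h (384 and 1972). With BR-49 the counts were 1985 and 2005 at 6 h, 1629 and 1652 at 24 h (1120 and 2345 as deposited) and 1259 and 1673 at 72 h (622 and 2823). With SL-08 they were 676 and 927 at 6 h (268 and 1960 as deposited), 1071 and 866 at 24 h, and 654 and 735 at 72 h (510 and 962). On chromosome 7, the locus at 187444 to 188928 stood at 6.75 scaled FPKM (interval 5.82 to 7.68) in uninfected roots without endophyte, 463 (452 to 474) at 6 h and 700 (686 to 714) at 24 h. With SL-08 the same locus stood at 17.4 before infection, 453 at 6 h and 245 at 24 h. On chromosome 6, the locus at 35331936 to 35332722 stood at 15.4 in uninfected SL-08 roots, 248 at 6 h and 261 at 24 h. Over the 3 inoculations this locus went from 28.6 ± 18.2 to 228 ± 28.5 at 6 h and was among the 14 called. With BR-49, the locus on chromosome 8 at 41872903 to 41873448 stood at 11.5 before infection, 204 at 24 h and 247 at 72 h, and the locus on chromosome 6 at 29776666 to 29777758 stood at 497 before infection, 5.04 at 6 h and 3.76 at 72 h, where the other 2 uninfected libraries had 33.0 and 29.0.

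**Figure D2:**
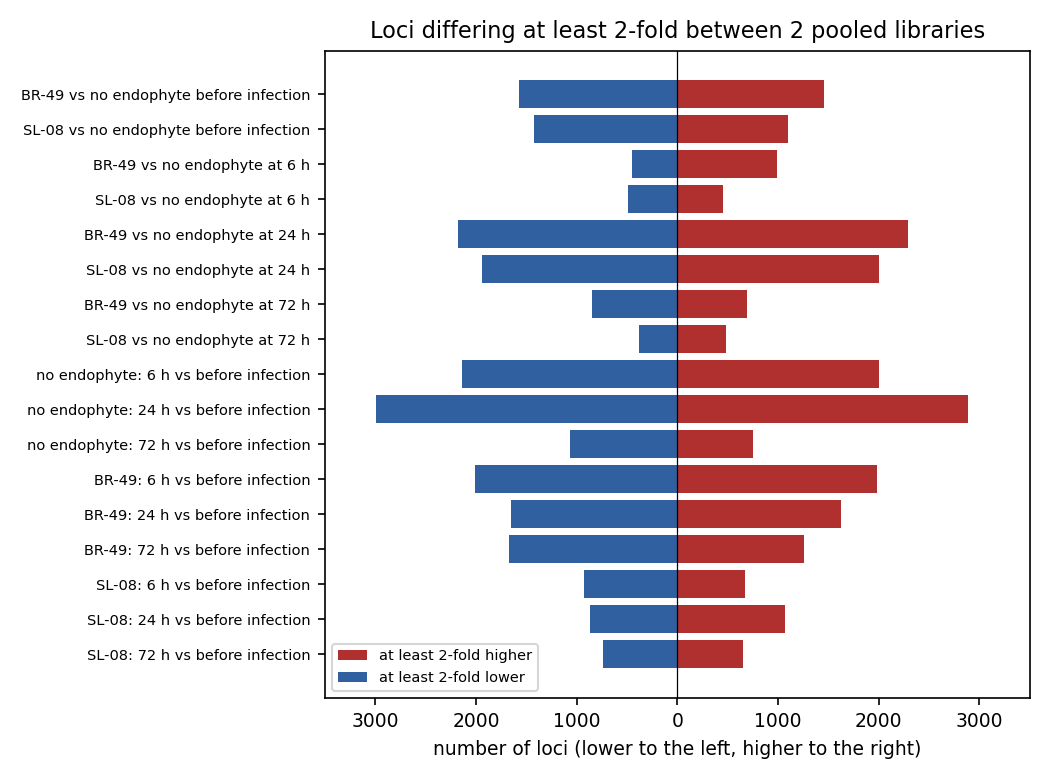
Number of loci at least 2-fold higher (right, red) or lower (left, blue) between 2 pooled libraries, with a scaled FPKM of at least 5 in 1 of the 2 (horizontal axis, number of loci), for each of the 17 comparisons (vertical axis). The counts ran from 481 higher and 380 lower for SL-08 at 72 h to 2883 higher and 2997 lower for the no-endophyte roots at 24 h against before infection, where the 24 h library is the one that lay apart.

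The infection responses of different inoculations were compared across loci, using pairs of libraries that share none; loci are not independent replicates, and no p is given. Of 9 such correlations of log2 ratios, 7 were above 0, with a median of 0.197. All 9 use the same 3 uninfected libraries as references, so they are not separate comparisons. At 72 h, the no-endophyte and BR-49 responses had r = 0.517, and 322 loci were at least 2-fold higher in both against 53.2 for independent lists. Another 446 were lower in both against 84.3. The SL-08 response at 72 h had r = 0.234 with that without endophyte and 0.162 with that of BR-49. At 6 h the no-endophyte and BR-49 responses had r = 0.428, no endophyte and SL-08 had 0.262, and BR-49 and SL-08 had -0.112. A technical difference shared by the uninfected libraries without endophyte and with BR-49 would also raise r between those 2. At 24 h, the no-endophyte and BR-49 responses had r = -0.164, with 982 loci changed at least 2-fold in opposite directions against 477 for independent lists. That comparison rests on the no-endophyte library that lay apart. It also rests on the uninfected BR-49 library, which correlated most with the one that lay apart (r = 0.855). BR-49 and SL-08, without the library that lay apart, had r = 0.0201. For the effect of an endophyte at different stages, 12 correlations ranged from -0.352 to 0.483 with a median of 0.00611. The highest was for BR-49 between uninfected roots and 72 h after infection (r = 0.483). The lowest was for BR-49 between uninfected roots and 24 h after infection (r = -0.352). This lowest value uses both the library that lay apart and the uninfected BR-49 library. Among the correlations without the library that lay apart, the lowest was -0.0821.

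Over all loci, stage took up 32.7% of the variance (exact permutation p = 0.130 over 576 arrangements, 0.129 from 100000 draws) and inoculation 16.1% (exact permutation p = 0.574 over 216 arrangements, 0.573 from draws); 27.3% and 18.2% would follow from their degrees of freedom alone. Without the no-endophyte library at 24 h, an alternative chosen after seeing the data, stage took up 38.9% (exact permutation p = 0.00174, the smallest the 576 arrangements can give) and inoculation 19.2% (exact permutation p = 0.250), where 30% and 20% would follow from the degrees of freedom. That library had 461 loci at least 1 log2 unit above and 863 below the range of the other 11. The first principal component held 29.6% of the variance and placed it at 118, the uninfected BR-49 library at 62.4 and the other 10 between -29.4 and 3.69. The second held 19.1% and placed the uninfected libraries without endophyte and with BR-49 at -81.8 and -53.2, and the uninfected SL-08 library at -11.4.

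**Figure D3:**
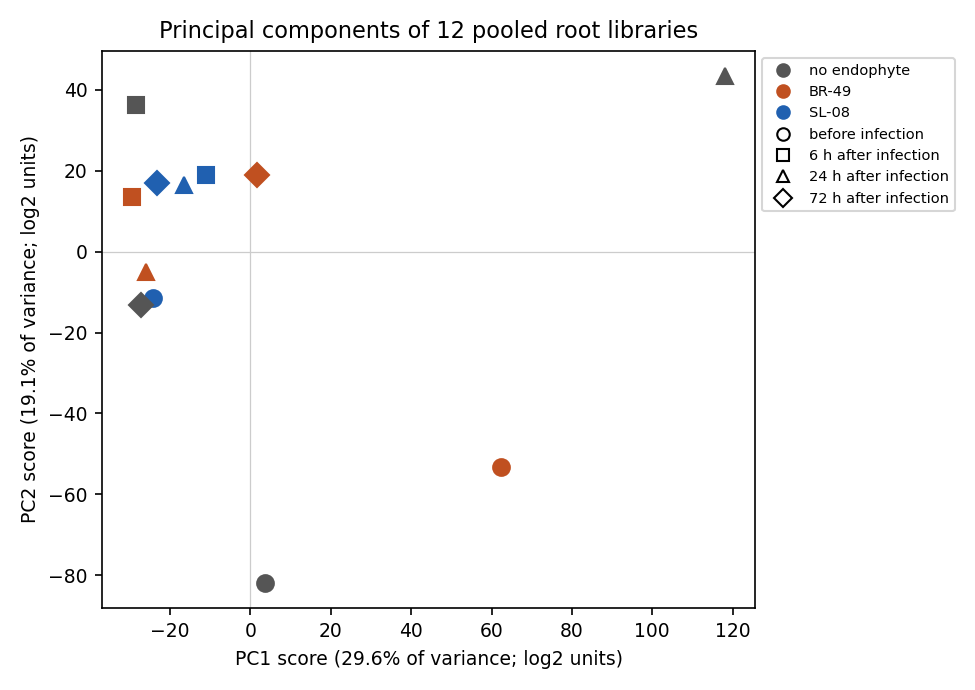
Scores of the 12 pooled libraries on the first and second principal components of log2 scaled FPKM (axes in log2 units, with the share of variance), coloured by inoculation and shaped by stage. The no-endophyte library at 24 h lies at 118 on the first component, and the uninfected no-endophyte library lies at -81.8 on the second.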

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

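The comparison of libraries and the exchange of labels described here were chosen only after the libraries had been seen to lie apart, with bounds set before each value was computed, except for the exchanges of the uninfected SL-08 library with 8 infected libraries; the splits of the libraries were counted after the calls were seen.

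Loci shorter than 300 bp were outside the comparisons, and 4 inoculated libraries listed such a locus above the highest in the libraries without endophyte (FPKM 270729). With SL-08 at 6 h this was a 152 bp locus on chromosome 8 at 44283788 to 44283940, with FPKM 4.70e+09. With BR-49 at 72 h it was a 14 bp locus on chromosome 5 at 11886694 to 11886708, with 2.33e+07. With either bacterium at 24 h it was a 101 bp locus on chromosome 9 at 37805256 to 37805357. Its FPKM was 294333 with BR-49 (interval 170975 to 417691) and 298721 with SL-08 (interval 173524 to 423918). Both intervals hold 270729, so these values do not stand clear of it. There were also more inoculated libraries than libraries without endophyte, so these maxima are no contrast between them.

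The no-endophyte library at 24 h after infection lay apart from the other 11, with a highest correlation across loci of 0.855 where each other library reached at least 0.890. Lower depth is argued against: among 2220 loci with a mean scaled FPKM of at least 50, 6.08% lay at least 1 log2 unit outside the range of the other 11 libraries, against a median of 0.135% in those. The mean was taken over all libraries, so loci high in this library alone could enter, and they were not counted apart. A loss that goes with locus span did not account for most of its departure, since 0.9996 of the variance of its deviation was left after a trend on span was removed. The median deviation still ran from -0.228 log2 units among the shortest loci (median span 647 bp) to 0.0611 among the longest (14523 bp). A slight loss of short loci is therefore not excluded. An exchange of labels within the series cannot account for its distance from the others, which is the same under any label. Whether the label of this library was exchanged with another was not decided. Exchanging it with the BR-49 library at 6 h, the uninfected SL-08 library or the BR-49 library at 24 h lowered the residual sum of squares of the additive model to 0.836, 0.845 and 0.878 of its value, the only ones below 0.9. These exchanges exclude each other, as moving a library that lies apart can lower the sum with several partners. A state of those plants, a sample from outside the series and a difference in handling were not tested.

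The uninfected SL-08 library correlated with the infected libraries of the other inoculations at a median of 0.919, against 0.867 and 0.857 for the uninfected libraries without endophyte and with BR-49. A candidate explanation is that SL-08 alone moved loci as infection did: its log2 ratio to the uninfected no-endophyte library correlated across loci with the BR-49 infection response, which shares no library with it, at r = 0.418. The same r would follow if the uninfected libraries without endophyte and with BR-49 shared a technical difference, and BR-49 in place of SL-08 gave r = 0.259 with the SL-08 response; the SL-08 ratio to the uninfected BR-49 library gave r = 0.124 with the no-endophyte response. Exchanges of its label with each of the 8 infected libraries other than the no-endophyte library at 24 h gave a residual sum of squares between 0.991 and 1.07 of its value, so that exchanging these labels hardly moved the sum and an exchange was not decided. The value of 0.845 with the no-endophyte library at 24 h decides nothing either, since that library gave values below 0.9 with 3 partners.

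Other splits of the libraries were drawn for each count of called loci, 100 with the real one, permuting the labels of a factor within the levels of the other. For 6 h after infection, 1 of the 100 splits, the real one, gave as many as 14, and the highest other gave 2. For 24 h, 1 of the 100, the real one, gave as many as 4, and the highest other gave 1. The real labels at 6 and 24 h thus gave more calls than any other split drawn. This does not exclude chance, since 1 of 100 is the lowest share these splits can give. It also says nothing of a single locus. The 6 h count fell to 0 without most of the single libraries, and the 24 h count without each one but the uninfected BR-49 library. For 72 h, for BR-49, SL-08 and their difference, and for both differences of the endophyte effect, the real count was 0, so that all 100 splits gave as many; the highest others were 2, 1, 1, 1, 5 and 3.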

How the results depend on the processing

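The counts for BR-49, SL-08 and SL-08 against BR-49 were 0 in every alternative run. The 6 h count was 14 (range 0 to 50 over single libraries left out, and 0 for most of them). It was 6 with a pseudocount of 0.1, 22 with no filter, 47 with no block and 7 at 90% overlap. The 24 h count was 4, and 0 with each library left out except the uninfected BR-49 library, where it was 4. It was 0 with a pseudocount of 0.1, 13 with no filter, 0 with a filter at FPKM 5 and 9 with non-robust empirical Bayes. With no block it was 14, at 80% overlap 7, and with only loci listed in all 12 libraries 2. The 72 h count was 0 (0 to 1 over libraries left out), and 1 with no filter and with no block. The count of differing BR-49 effects was 0 (0 to 1 over libraries left out), 6 with a pseudocount of 0.1, 2 with no filter, 2 at 80% and 1 at 90% overlap; that of SL-08 effects was 0 (0 to 0), 3 with a pseudocount of 0.1, 2 at 80% and 1 at 90% overlap. Of all loci called for these effects in any alternative, 0 were listed in all 12 libraries, and a smaller pseudocount widens the distance from an absent locus. For the rest the cause was not tested. The overlaps and the loci listed in all 12 libraries were chosen after seeing the data. The interaction could not be fitted for an inoculation without its uninfected library, nor for either without the uninfected no-endophyte library.

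Of 660 alternative values of the named loci, all 660 kept their direction. The loci were chosen by p-value or size of change in these same libraries, so this follows in large part from the choice. Of the values, 62 lost the threshold and 14 gained it, and only values of loci called above could lose it. The named loci called at 6 h passed it in between 11 of 21 and 14 of 22 alternatives. Those called at 24 h passed it in 9 of 22 and 8 of 21. The adjusted p of the locus on chromosome 10 at 7616450 ran from 0.00425 to 0.168 at 6 h. Stage took up 38.9% of the variance without the no-endophyte library at 24 h, against 32.7% (30% and 27.3% from the degrees of freedom); only that library was left out there, a choice made after seeing the data. Of 51 alternative counts of 2-fold loci, 45 were within 1.5 times; with a minimum FPKM of 1, which admits more loci, BR-49 had 2217 at 6 h and 2400 at 72 h, SL-08 had 1777 and 1510, and SL-08 against its uninfected library had 2431 at 6 h and 2152 at 72 h. The gene lists and their alternatives were not run, as no names were paired. No paired analysis was possible because the labels give no replicate numbers that groups share; the inoculation entered as a block, and without it the counts were those given above. Depth limits what an absent locus means, since a low level and a value left out upstream look alike.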

Other observations

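The tests in this part were chosen after the data were seen, and the bound for neighbouring loci was set after its value was computed. Loci were counted where all libraries of a stage lay at least 1 log2 unit from all others. Uninfected roots had 10 loci above and 1 below the 9 infected libraries, 11 in all, and the highest of the 60 other choices of 1 library per inoculation gave 9. The median of the other choices was 1. At 72 h after infection 3 loci lay above the other 9 libraries. Among the 60 other choices and the real one together, 13 gave a number as large, and the highest of the 60 gave 9. Of these 3 loci, the one on chromosome 2 at 19432242 to 19433874 had 66.9 ± 9.31 scaled FPKM (SD, n = 3) against 14.5 ± 6.85 (n = 9). The one on chromosome 3 at 26663524 to 26664348 had 123 ± 19.2 against 33.3 ± 11.3. The locus on chromosome 1 at 7118567 to 7120049 stood between 0 and 5.36 in uninfected roots, with 0 meaning not listed, and between 14.1 and 31.1 in infected ones. The loci named here were chosen after their values were seen.

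The 27 loci on contigs named as mitochondrial had, relative to each locus's own median, a median log2 level of 1.46 in the no-endophyte library at 24 h, 1.12 in the SL-08 library at 6 h and -0.65 in the uninfected no-endophyte library. On the 11 numbered chromosomes the library medians lay between -0.01 and 0.03. The scaling brings these medians together by design, so they are no separate check. The 10 most abundant loci held 16.4% of the summed scaled FPKM in the no-endophyte library at 24 h and between 6.54% and 12.3% in the others.

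Some loci were absent from single libraries at high levels elsewhere. A locus on the contig of unplaced sequence at 46030627 to 46033353 stood at 1451, 6338, 7162 and 7593 scaled FPKM in 4 libraries and was not listed in the other 8, and the locus on chromosome 6 at 14310766 to 14313412 stood between 175 and 1349 in 7 libraries and was not listed in 5. Of the loci with at least 10 in 11 libraries, 14 were not listed in the other 1, 6 of them in the no-endophyte library at 24 h, and 0 were listed there at under 1. Of all listed loci of at least 300 bp, 3.03% had FPKM under 1, so that low levels were seldom listed at all. A value left out upstream and a level under what the assembler reports therefore cannot be told apart.

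Neighbouring loci were asked whether they moved together, and only loci kept after joining were compared. The median correlation of residuals over the 12 libraries was 0.041 for 15957 adjacent pairs within 10000 bp and 0.0061 for pairs on different chromosomes, an excess of 0.0349. This argues against a general excess of 0.1 or more among those loci, and says nothing of the 23428 loci left out for another shape in some library.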
